A study of Rattus norvegicus with 6 samples.

How the data were processed

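Small RNA libraries of rat myocardial cells were analysed in 2 groups, 3 control and 3 hypoxia/reoxygenation (H/R) libraries, assigned from the sample titles and the treatment in the labels. The deposited table gives reads-per-million (RPM) values for each library, rounded to 2 decimals, with the sequence, its length in nucleotides and a list of target gene identifiers. No header names the unit: it was inferred from the values, which are whole multiples of a single step in each. Reads were processed with CASAVA, per the submitters' processing notes, which give no version. The aligner, the miRNA caller, the miRBase release, the genome build and the rule for target genes are not given in the sources used here. The deposited table gives RPM without read counts, so whole reads were recovered by taking the smallest step as 1 read. The share of values that came out whole was 100% in every library, within a tolerance of 0.0051 RPM.

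The library totals recovered in this way ranged from 732617 to 3413757 reads, of which the listed sequences held 79.6% to 82.7%. A single read is 0.293 to 0.44 RPM in the controls and 1.36, 0.465 and 0.921 RPM in H/R replicates 1 to 3. A floor of 3 reads is 0.88, 1.32 and 1.04 RPM in control replicates 1 to 3 and 4.09, 1.39 and 2.76 RPM in H/R replicates 1 to 3. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The table holds 761 distinct sequences in 790 entries, and 29 entries repeat a sequence under another name; each name was tested, and counts by distinct sequence are given where named so. let-7a-1-3p and let-7c-2-3p, for example, are the same sequence. Predicted sequences are identified by their sequence.

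The design fixed before the data were examined allowed for counts, with edgeR as the main test, or for normalised values. The values are RPM, so the main test was limma (version 3.58.1, trend, not robust) on log2(RPM + 1), two-sided, for sequences with at least 1 RPM in at least 3 libraries, with Benjamini-Hochberg adjusted p under 0.05 and no fold-change threshold. edgeR's quasi-likelihood test with TMM scaling on the recovered reads, added after the unit was known, called 64 of 415 sequences, 57 of them shared with limma. Lists of miRNAs were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and fry as alternatives, for the 16 of 19 lists with at least 3 tested members, and adjusted over these lists. The lists were hypoxia-induced miR-210, muscle miRNAs, let-7/miR-98, miR-15/16, miR-17-92 and its paralogues, miR-29, miR-30, miR-23/27/24, miR-221 with miR-222, miR-181, p53-responsive, inflammation-linked, cardiac ischaemia/reperfusion, fibroblast and mesenchymal, endothelial, blood-cell, neural, epithelial and liver, and Dlk1-Dio3 miRNAs. Measures of whole libraries were compared with a two-sided exact permutation test, which cannot give less than 0.1 with 3 against 3 libraries.

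The miRNAs named were fixed by rule before the data were examined: the 10 largest positive and 10 largest negative log2 fold changes among calls with a mean of at least 10 RPM and no overlap between groups, the 10 most abundant sequences, fixed miRNAs of heart muscle, hypoxia and p53 (miR-210-3p, miR-1-3p, miR-133a-3p, miR-208a-3p, miR-499-5p, miR-21-5p and miR-34a-5p), and of each list up to 4 called members and the most abundant. Others are said to be chosen after their values were seen, or are partner arms of named hairpins or list members counted by a tool. No pair of libraries agreed within sampling noise, so none was treated as a copy of another, which does not show that they came from separate cultures.

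On data simulated for this comparison, 574 sequences tested with 190 changed, limma recovered 26% of 96 changes of 1 log2 unit and 90.4% of 94 changes of 2 log2 units, and 2.7% of its 113 calls were false. With no change simulated it made 0 calls among 590 sequences. Camera found the 1 list raised by 1 log2 unit and 0 others. Each sequence was drawn independently with 1 common dispersion, 0.109, and without outlying libraries. The simulation thus cannot show how camera or the share of false calls behaves when sequences are correlated or single libraries stand out.

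Alternatives covered scaling, the filter on low values, the pseudocount, DESeq2 (version 1.42.0), edgeR (version 4.0.16), limma-voom, each library left out in turn, the replicate number as a block, known miRNAs alone, thinned reads and 1 entry per sequence. Analyses ran in R 4.3.3 and Python 3.11.15 with scipy 1.17.1. Enrichment of the authors' target lists was not analysed here, because their gene identifiers could not be paired with names from the gene table used, and genome positions are not given.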

Results

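Small RNA was sequenced from cultured rat myocardial cells in 2 groups of 3 libraries each. Control cells grew in complete medium under normal oxygen. The hypoxia/reoxygenation (H/R) group, a culture model of ischaemia followed by reperfusion, spent 6 h in glucose-free medium at 1% O2 and then 16 h with oxygen restored. The table analysed here gives reads-per-million (RPM) values for 790 mature sequences, of which 529 carry the name of a known rat miRNA and 261 are sequences predicted by the authors. The library totals implied by the values were 3413757, 2274255 and 2892749 reads for control replicates 1 to 3 and 732617, 2151661 and 1086304 reads for H/R replicates 1 to 3. The mean total was 2860254 ± 570446 reads in controls and 1323527 ± 738666 in H/R (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). Nothing in the labels states whether the replicates of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

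The comparison of H/R with control asks which miRNAs respond to oxygen and glucose deprivation followed by reoxygenation. Among known miRNAs 25 were lower and 4 higher in H/R, and at least 21 of the 25 were the less abundant arm of their hairpin. The -5p strands of miR-27a and miR-222 and the -3p strands of miR-181b-1, miR-26b and miR-145 fell, while the opposite strands of the same hairpins did not pass the test. miR-503-5p, a member of the miR-15/16 seed family that restrains cell-cycle genes, was the most abundant known miRNA that rose. Predicted sequences moved the other way, with 50 higher and 5 lower, and most of those that rose were 17 or 18 nt long.

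Of 571 sequences with at least 1 RPM in at least 3 libraries, 84 passed the threshold of the limma test, 54 higher and 30 lower in H/R. The 370 known miRNAs tested held 4 of the higher and 25 of the lower calls. The 2 groups of libraries did not overlap for 187 sequences, 32.7% of those tested, where chance gives 10%. The count of 84 fell to 54 without control replicate 1, to 28 without H/R replicate 2 and to 39 without H/R replicate 3. Known miRNAs called lower numbered 13 without control replicate 1 or H/R replicate 2, 16 without H/R replicate 3 or with a filter of 50 reads in 3 libraries, and 35 without H/R replicate 1, and 1 was called higher without control replicate 1 or H/R replicate 2 or 3. A test of known miRNAs only called 17 lower and 1 higher. Predicted sequences called higher numbered 10 without H/R replicate 2, 19 without H/R replicate 3, 17 with the 50-read filter, and 30 and 33 with edgeR (upper-quartile and TMM scaling). Those called lower numbered 3 without control replicate 2 or 3 or H/R replicate 3, and 4 when any other single library was left out. The share of calls that were higher, 64.3% in the limma test, thus depends on the setting: 39.3% without H/R replicate 2, 49.4% without H/R replicate 1, 51.3% without H/R replicate 3, 47.4% with the 50-read filter and 50.8% with upper-quartile scaling of the recovered reads (edgeR).

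The fall of minor arms was large for several hairpins. miR-27a-5p went from 231.8 ± 17.6 RPM in controls to 27.6 ± 5.27 RPM in H/R (SD, n = 3 each), a log2 fold change of −3.04 ± 0.222 (SE; limma adjusted p = 0.000343). miR-27a-3p, its partner, stood at 8537 ± 2380 and 8596 ± 1020 RPM (limma adjusted p = 0.937). miR-222-5p went from 51.7 ± 11.5 to 4.13 ± 1.17 RPM, a log2 fold change of −3.36 ± 0.298 (limma adjusted p = 0.000669), and miR-222-3p stood at 1323 ± 578 and 1189 ± 494 RPM. miR-181b-1-3p fell from 30.1 ± 2.64 to 2.91 ± 0.292 RPM, miR-152-5p from 134.4 ± 23.3 to 25.6 ± 4.05 RPM and miR-26b-3p from 19.6 ± 1.71 to 3.52 ± 0.686 RPM, with limma adjusted p-values of 0.000568, 0.000942 and 0.00177. In H/R replicates 1 to 3, miR-181b-1-3p had 2, 7 and 3 reads, miR-26b-3p 3, 8 and 3 and miR-222-5p 4, 7 and 4. The SDs of such low counts are imprecise. The H/R means of miR-181b-1-3p and miR-26b-3p lie below the 4.09 RPM that 3 reads represent in H/R replicate 1. miR-145-3p, from the miR-143/145 cluster of smooth muscle and fibroblasts, was abundant on both sides and fell from 2281 ± 61.7 to 923.1 ± 121 RPM, a log2 fold change of −1.31 ± 0.161 (limma adjusted p = 0.00177). All log2 fold changes are on the scale of log2(RPM + 1), which understates the change of sequences near 1 RPM.

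**Figure D1:**
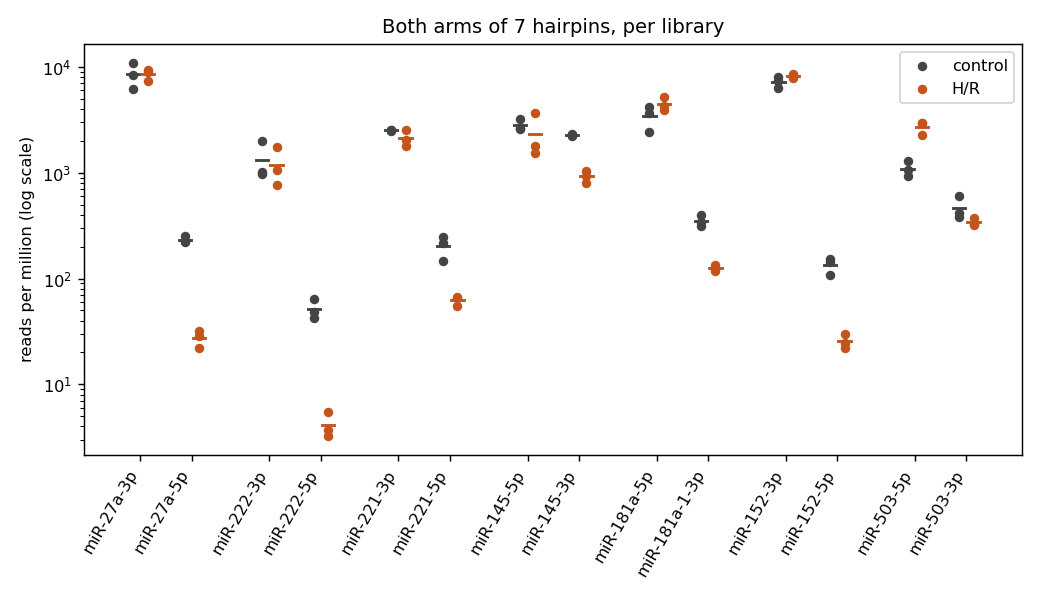
RPM (log axis) of both arms of 7 hairpins in each library, with control libraries in grey, H/R libraries in orange and a bar at each group mean. miR-27a-5p lies near 231.8 RPM in controls and 27.6 RPM in H/R while miR-27a-3p lies near 8537 and 8596 RPM; miR-503-5p is the arm that rises, from 1094 to 2726 RPM.

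miR-224-5p had the most negative log2 fold change of the known miRNAs, −5.02 ± 1.13 (limma adjusted p = 0.0235), but its control libraries ranged from 8.64 to 233.2 RPM. It had 949 reads over the controls and 3 over the H/R libraries, a ratio of 0.00683 with an exact 95% interval of 0.00141 to 0.02 for counting error only. Its call was lost without control replicate 1 or 2 and without H/R replicate 1 or 2, with adjusted p-values of 0.0513 to 0.0994. With all libraries it was lost with a replicate block (0.0521), limma-voom (0.058), known miRNAs only (0.0561) and pseudocount 10 (0.0763, log2 fold change −2.63).

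The known miRNAs that rose were few. miR-503-5p went from 1094 ± 175 to 2726 ± 396 RPM, a log2 fold change of 1.32 ± 0.193 (limma adjusted p = 0.00369), whereas miR-503-3p stood at 465.2 ± 115 and 341.3 ± 30.3 RPM. miR-193a-3p rose from 8.31 ± 4.61 to 26.8 ± 4.18 RPM (log2 fold change 1.73 ± 0.46, limma adjusted p = 0.0477), and lost its call when control replicate 1 or any of the H/R replicates was left out, with adjusted p-values of 0.0846 to 0.143. It was also lost with known miRNAs only (0.0931), without a filter (0.0653), at pseudocount 0.1 (0.0648) and without the 10 most abundant sequences (0.0581). miR-1949, at 2.13 ± 0.336 and 7.05 ± 0.757 RPM, and miR-196b-3p, at 1.27 ± 0.214 and 3.83 ± 0.226 RPM, also passed and are named after their values were seen. Neither was called with known miRNAs only or without control replicate 1, H/R replicate 2 or H/R replicate 3. In each of these settings miR-503-5p was the only known miRNA called higher. The 3.83 RPM of miR-196b-3p lies below the 4.09 RPM that 3 reads represent in H/R replicate 1.

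The miRNA lists fixed in advance were tested with limma's camera. The miR-23/27/24 clusters, the miR-30 family and the paired miR-221 and miR-222 hairpins were lower as lists, with adjusted p-values of 0.0251, 0.0485 and 0.0485 at the preset correlation of 0.01. None of these calls held when the correlation was estimated, with adjusted p = 0.474, 0.868 and 0.623 in the same order. With known miRNAs only, the miR-23/27/24 list and that of miR-221 and miR-222 were called (0.042 and 0.0424; 0.625 for both with an estimated correlation) and miR-30 was not (0.0821). No list was called with edgeR or limma-voom, and without H/R replicate 1 none of the 3 passed (adjusted p = 0.069 to 0.0815). The miR-30 list was also lost when control replicate 1 or 3 or H/R replicate 2 or 3 was left out, and the miR-221 and miR-222 list without control replicate 3 or H/R replicate 3 (adjusted p = 0.0795 to 0.148 in these cases). In the miR-23/27/24 clusters 3 of 11 tested members fell, miR-27a-5p, miR-27b-5p (23.9 ± 4.19 to 5.98 ± 2.12 RPM) and miR-23a-5p (13.9 ± 5.95 to 3.37 ± 1.06 RPM). miR-24-3p, the most abundant member, stood at 20090 ± 277 and 19740 ± 1030 RPM. Of the miR-221 and miR-222 arms 2 of 4 fell, miR-222-5p and miR-221-5p (202.8 ± 50.1 to 62.1 ± 6.55 RPM), and miR-221-3p stood at 2522 ± 20.7 and 2116 ± 390 RPM. In the miR-30 family 1 of 10 fell, miR-30c-2-3p (57.0 ± 7.53 to 15.5 ± 7.39 RPM), with 3 passing when adjusted over the list alone; miR-30e-5p, its most abundant member, stood at 5512 ± 1370 and 4395 ± 1240 RPM. Of the miR-30 members edgeR with TMM scaling called 3, limma-voom 2 and DESeq2 1. The members that fell in these 3 lists are the strands usually discarded when the hairpin is loaded, so they are not the ones the lists are best known for. The calls of miR-23a-5p and miR-30c-2-3p were lost without control replicate 1 (adjusted p = 0.0633 and 0.0726) or H/R replicate 2 (0.0938 and 0.0557), and that of miR-30c-2-3p also without control replicate 3 (0.0563). The call of miR-23a-5p was also lost with known miRNAs only (0.053) and with thinned reads (0.102), and that of miR-27b-5p with thinned reads (0.0606).

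Single members were called in 4 other lists. In the miR-181 list 1 of 7 fell, miR-181a-1-3p (350.7 ± 42.9 to 125.2 ± 7.81 RPM), and miR-181a-5p stood at 3424 ± 914 and 4460 ± 677 RPM; the median log2 fold change of this list was 0.027 and its mean −0.116. This list leaves out miR-181b-1-3p, which fell as given above, and the fibroblast list leaves out miR-152-5p, which also fell. Among the listed fibroblast and mesenchymal miRNAs 1 of 10 fell, miR-145-3p, while miR-143-3p stood at 58800 ± 7470 and 54370 ± 6780 RPM. In the miR-15/16 family 1 of 7 rose, miR-503-5p, and miR-16-5p stood at 5050 ± 1040 and 5745 ± 823 RPM. Among the muscle miRNAs 1 of 7 tested was called lower, miR-133b-5p, with 19 reads over the controls and 0 over the H/R libraries, at least 2.93-fold lower against a floor of 3 reads over the group. That floor is 0.756 RPM, yet 3 reads in H/R replicate 1 alone are 4.09 RPM, above the control mean of 2.27 RPM. The call of miR-133b-5p was lost without H/R replicate 2 or 3 (adjusted p = 0.0627 and 0.0755), with known miRNAs only (0.0671) and with DESeq2 (0.195). The filter of edgeR and limma-voom removed it, so these tools did not test it. For each list described so far except the miR-30 family, the number called when adjusted over the list alone was the same as over all sequences. The camera adjusted p-values of the miR-181, fibroblast, miR-15/16 and muscle lists were 0.793, 0.437, 0.437 and 0.437. With known miRNAs only, the miR-15/16 list was called higher (0.0309), a call lost with an estimated correlation (adjusted p = 0.625). fry called the fibroblast list lower (0.00747), and camera did not with an estimated correlation (adjusted p = 0.868).

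None of the tested miRNAs of muscle, hypoxia and p53 described in this paragraph passed the test, whereas the muscle miRNA miR-133b-5p, given above, did. miR-210-3p, induced by hypoxia-inducible factor in many cell types, stood at 17.4 ± 9.44 RPM in controls and 26.7 ± 2.5 RPM in H/R, a log2 fold change of 0.73 ± 0.424 (limma adjusted p = 0.325), and miR-210-5p at 1.96 ± 1.03 and 0.767 ± 0.958 RPM. The muscle miRNAs miR-1-3p, miR-133a-3p and miR-206-3p stood at 50.4 ± 18, 788.3 ± 271 and 3225 ± 291 RPM in controls against 40.0 ± 2.29, 675.6 ± 147 and 2980 ± 131 RPM in H/R. miR-499-5p, encoded in a myosin heavy chain gene, stood at 49.0 ± 6.67 and 57.9 ± 1.97 RPM. miR-208a-3p, which marks adult cardiomyocytes, had 1 read over the controls and 0 over the H/R libraries and was not tested. miR-34a-5p, which p53 induces, stood at 348.2 ± 139 and 414.1 ± 7.89 RPM. miR-133a-3p and miR-133b-3p differ at the 3′ end alone and lay within 4.8% of each other in each of the 6 libraries, so both values are uncertain.

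Of 40 tested miRNAs reported in cardiac ischaemia/reperfusion, 0 passed the limma test or had an unadjusted p under 0.05, and 0 were called by edgeR, DESeq2 or limma-voom. Their median log2 fold change was −0.028 and their mean 0.105, with a camera adjusted p of 0.907. With known miRNAs only, camera called this list higher (adjusted p = 0.0435, and 0.703 with an estimated correlation), and it was called under no other alternative. The same count of 0 held for the 9 tested let-7/miR-98 members, all -5p arms (camera adjusted p = 0.468), of which let-7f-5p stood at 16110 ± 5130 and 11440 ± 1670 RPM, and for the 6 tested members of the miR-29 family (0.722), of which miR-29a-3p stood at 18140 ± 3400 and 18110 ± 105 RPM. In the miR-17-92 and paralogous clusters 0 of 16 passed any of these tools, with 2 at an unadjusted p under 0.05, a median log2 fold change of −0.022, a mean of 0.059 and a camera adjusted p of 0.888; miR-25-3p stood at 6802 ± 551 and 6823 ± 1080 RPM. Of 10 inflammation-linked miRNAs 0 passed any of these tools, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.556). Of 10 p53-responsive miRNAs 0 passed the limma test, with 1 at an unadjusted p under 0.05 and 1, miR-34b-5p, called by DESeq2 (camera adjusted p = 0.56). Of the Dlk1-Dio3 imprinted cluster 28 members were listed and 1 was tested, miR-127-3p, at 2.25 ± 1.86 and 0.76 ± 0.694 RPM. For all of these lists the number called when adjusted over the list alone was also 0. The lists leave out some arms of the same hairpins, which were looked up after their values were seen. Of these, 5 of 11 tested -3p arms were called lower for let-7/miR-98 (2 of the 5 have the same sequence), 4 of 26 arms for cardiac ischaemia/reperfusion, 2 of 5 for the inflammation-linked and 1 of 2 for the p53-responsive miRNAs. For the neural list described below it was 1 of 2. It was 0 of 5 for the miR-15/16 family and 0 of 2 for the miR-17-92 and paralogous clusters.

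None of the known miRNAs among the 10 most abundant sequences passed the test. miR-21-5p, the top sequence, stood at 119900 ± 18600 RPM in controls and 101800 ± 17700 RPM in H/R, a log2 fold change of −0.24 ± 0.196 (limma adjusted p = 0.486). miR-99a-5p stood at 40300 ± 2420 and 37030 ± 9880 RPM, miR-199a-3p at 25500 ± 2150 and 28550 ± 1650 RPM, miR-125b-5p at 24480 ± 2750 and 25280 ± 313 RPM, miR-199a-5p at 25050 ± 5480 and 20270 ± 1880 RPM, and miR-26a-5p at 23530 ± 3890 and 17520 ± 1070 RPM. miR-99b-5p stood at 26880 ± 6450 and 20510 ± 10400 RPM. The 10 most abundant sequences took 47.1% ± 0.59 of the reads in the listed sequences in controls and 45.9% ± 1.45 in H/R (SD, n = 3; two-sided exact permutation p = 0.3).

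Predicted sequences made up 7.96% ± 0.99 of all reads in controls and 13.2% ± 1.11 in H/R, and those of 17 nt alone 6.26% ± 0.99 and 11.3% ± 0.88 (SD, n = 3; two-sided exact permutation p = 0.1 for each, the smallest possible). Some predicted sequences repeat most of a known miRNA. For miR-378a-3p, miR-484 and miR-214-3p the reads of such a sequence lay within 0.0%, 4.6% and 9.0% in each library. Other predicted sequences had reads within 0.5% to 1.7% of each other. Whether the same reads were counted more than once was not tested, so these shares may be too high. By distinct sequence, 34 of 88 predicted sequences of 17 or 18 nt rose and 3 fell, 13 of 45 of 19 to 21 nt rose and 2 fell, and 1 of 45 of 22 to 25 nt rose and 0 fell. The median log2 fold changes of these length classes were 1.02, 0.17 and −0.28. The most abundant, UGGGUGCUGUAGGCUUU, rose from 20230 ± 2550 to 44890 ± 5570 RPM, a log2 fold change of 1.15 ± 0.171 (limma adjusted p = 0.00369). CAGGUGCUGUAGGCUUU, which shares its last 15 nt, rose from 10060 ± 2100 to 21700 ± 2610 RPM; how the authors' counting divides reads between such sequences is not given, so both values are uncertain. CAGGUGCUGUAGGCUUU is named after its values were seen.

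The steepest rises with a mean of at least 10 RPM were CUGGAAAUUCUGUUGGU, from 2.29 ± 1.71 to 68.9 ± 3.78 RPM (log2 fold change 4.57 ± 0.458, limma adjusted p = 0.000932), and GAGGAGAUAAAUAUGAGA, from 3.99 ± 0.486 to 108.0 ± 17.6 RPM (4.44 ± 0.247, limma adjusted p = 0.000188). GGCGCGGGAAAUGUGGC rose from 852.5 ± 300 to 2727 ± 57.4 RPM, UUGCACUCAGGAGGUAG from 187.3 ± 68.9 to 770.0 ± 242 RPM, UGGUAGAGCACUUGGUC from 194.2 ± 35.6 to 504.9 ± 55.0 RPM, ACAGGGCUUUAUUUUCU from 31.2 ± 2.8 to 116.0 ± 42.1 RPM and AUUCCCUUCACCUGCUCA from 11.4 ± 1.52 to 34.6 ± 11.4 RPM. The call of AUUCCCUUCACCUGCUCA was lost without control replicate 1 or H/R replicate 2, with adjusted p = 0.0513 and 0.0526. GAGAUGUAGCUCAGCUU rose from 505.9 ± 184 to 1984 ± 261 RPM and GGAGAAGUAGCUCAGCC from 535.0 ± 185 to 2022 ± 271 RPM; their reads lay within 9.1% of each other in each of the 6 libraries, and whether the same reads were counted for both was not tested.

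Of the 48 distinct predicted sequences that rose, 14 had 0 reads in all 3 control libraries, although these were the deeper ones, and 9 more had 1 to 3 control reads in all. The 14 had 8 to 50 reads over the H/R libraries and were at least 5.76-fold to at least 36.0-fold higher against a floor of 3 reads over the control group, 0.35 RPM. The highest of them, UGUUGUUCUGAAAGUUU, had 50 H/R reads, between 9 and 24 in each library, and stood at 13.03 ± 2.34 RPM. It is named after its values were seen.

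Among predicted sequences that fell, UUGGUACCUGUUUCCUGUUU went from 58.5 ± 11.5 to 4.13 ± 1.62 RPM, AUGUGUGUUUUUUUGAUA from 34.2 ± 6.87 to 3.38 ± 1.1 RPM and GUGGUGUGUUAGUUACUUUUC from 257.8 ± 25.4 to 42.3 ± 2.75 RPM, with limma adjusted p-values of 0.000779, 0.000932 and 0.000343. The first 2 rest on few reads in H/R replicates 1 to 3, 4, 5 and 5 reads and 2, 10 and 3 reads. No genome was used here, so the origin of the predicted sequences and their positions are not given, beyond the matches to known miRNAs above.

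**Figure D2:**
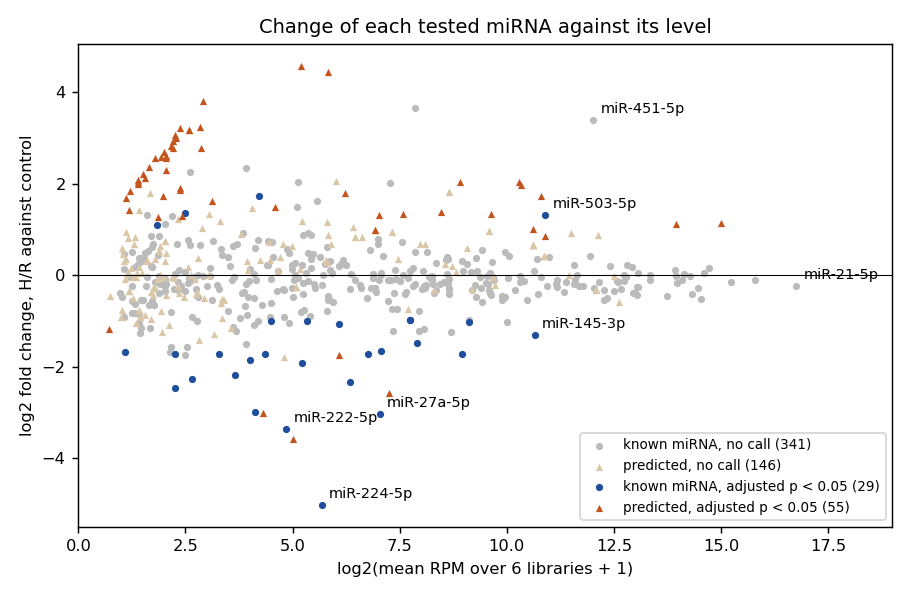
Log2 fold change of H/R against control on the log2(RPM + 1) scale (vertical axis) plotted against the log2 mean level over the 6 libraries (horizontal axis) for the 571 tested sequences, with known miRNAs as circles, predicted sequences as triangles and those past the limma threshold in blue or orange. The 25 known miRNAs called lower lie below the line at 0, and the 50 predicted sequences called higher lie above it, many of them at low level.

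Markers of other cell types stood far above all other libraries in single H/R libraries, and these differences between libraries of 1 group enter each list they belong to. H/R replicate 3 had miR-451-5p, an erythroid miRNA, at 24621 RPM (26746 reads) against at most 51.9 RPM elsewhere, and miR-486 and miR-144-3p, also of red cells, at 2930 and 1343 RPM. H/R replicate 2 had the neural miRNAs miR-9a-3p, miR-124-3p and miR-9a-5p at 267.7, 229.6 and 158.0 RPM. H/R replicate 1 had miR-122-5p, the main miRNA of hepatocytes, at 905.0 RPM (663 reads) against at most 3.08 RPM elsewhere, and miR-200a-3p of epithelia at 76.4 RPM. By group, miR-451-5p stood at 31.3 ± 6.5 RPM in controls and 8233 ± 14200 in H/R (limma adjusted p = 0.406), and miR-122-5p at 2.61 ± 0.406 and 302.4 ± 522 RPM (limma adjusted p = 0.612). Apart from miR-451-5p and miR-122-5p, the markers named in this paragraph were chosen after their values were seen.

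None of the lists of other cell types was called by camera, with adjusted p-values of 0.437 for 6 tested blood-cell miRNAs, 0.722 for 6 neural and 0.662 for 6 epithelial and liver miRNAs, and 0 members passed the limma test, over all sequences or adjusted over the list alone, or had an unadjusted p under 0.05. The filter of edgeR (TMM) and limma-voom kept only 4 blood-cell, 3 neural and fewer than 3 epithelial and liver miRNAs. Both tools called 0 of those kept. DESeq2 called miR-9a-5p and miR-200a-3p. The blood-cell list was called higher without H/R replicate 2 (adjusted p = 0.0347) and with known miRNAs only (0.042), and both calls were lost with an estimated correlation (adjusted p = 0.894 and 0.703). The pair of endothelial miRNAs tested did not pass in any tool, with miR-126a-3p at 188.8 ± 19.2 and 273.8 ± 65.6 RPM. Of the fixed markers in the table, 2 of 9 blood-cell (miR-451-5p and miR-486), 2 of 6 neural (miR-128-3p and miR-219a-5p) and 0 of 9 epithelial and liver miRNAs had at least 10 RPM in controls, and miR-486, miR-150-5p, miR-122-5p and miR-200c-3p also belong to the cardiac ischaemia/reperfusion list. miR-128-3p stood at 880.6 ± 250 and 1247 ± 665 RPM.

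**Figure D3:**
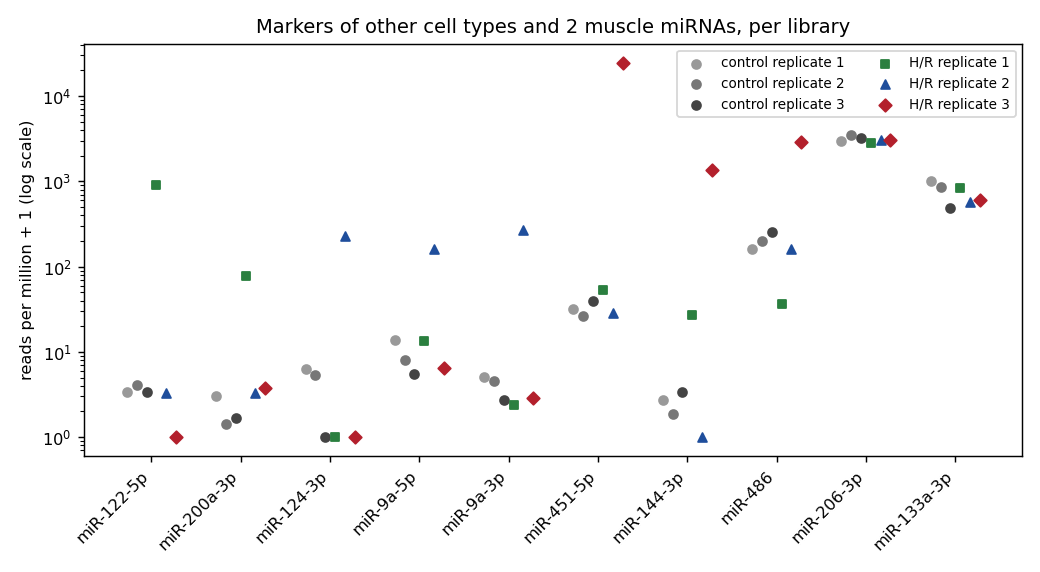
RPM + 1 (log axis) in each library of 8 markers of liver, epithelium, neural tissue and blood and of the muscle miRNAs miR-206-3p and miR-133a-3p. miR-122-5p reaches 905.0 RPM in H/R replicate 1 alone, miR-124-3p 229.6 RPM in H/R replicate 2 alone and miR-451-5p 24621 RPM in H/R replicate 3 alone. The markers other than miR-122-5p and miR-451-5p were chosen after their values were seen.

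The number of sequences with at least 1 read was 648.0 ± 21.6 in controls and 588.3 ± 34.3 in H/R (SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible). After thinning all libraries to 595794 reads in the listed sequences it was 543.0 ± 15.7 and 553.0 ± 3.61 (exact permutation p = 0.4). The authors' lists of target genes held 709 distinct gene identifiers for the known miRNAs that fell, of which 18 of 25 had any target listed, and 105 for the 4 that rose.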

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

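Rescaled RPM (by TMM factors or to the known miRNAs), thinned reads, 1 entry per sequence and edgeR with TMM scaling were added after the data were seen. The count of 84 calls stayed within 1.5 times itself under 16 of 19 alternatives that keep all libraries. It was 38 with at least 50 reads in 3 libraries and 18 with known miRNAs only, both of which test fewer sequences, and 162 at an unadjusted p. Leaving out 1 library gave 28 to 80 calls. Rescaling to the known miRNAs moved the median log2 fold change of all sequences by 0.126 and gave 4 known miRNAs higher and 21 lower, with predicted sequences at 57 higher and 5 lower. The 3 lists called fell to 0 with edgeR (TMM, RLE, upper quartile or library size only), limma-voom, the 50-read filter, thinned reads or an estimated correlation. They fell to 1 without a filter, with a replicate block, without the 10 most abundant, at pseudocount 0.1, with either rescaling or with 1 entry per sequence, and rose to 5 with known miRNAs only, where miR-30 was lost and miR-15/16, cardiac and blood-cell lists were called higher (none with an estimated correlation); leaving out 1 library gave 0 to 3. fry called 3, with the fibroblast list (adjusted p = 0.00747) in place of miR-30 (0.0671). The cause was not tested. The difference in sequences detected, −59.7, became 10.0 after thinning, so it follows depth. Of 614 alternative values of the called named miRNAs, 584 kept the call and direction and 30, in 7 miRNAs, lost the call; 0 reversed. Settings in which a miRNA was not tested are left out of these counts: miR-133b-5p had 13 alternatives and miR-503-5p 23. Many of these miRNAs were named for their large changes, so the counts do not describe all 84 calls. The replicate numbers did not pair the libraries: same-number deviations correlated at −0.03, 0 and 0.04. The replicate block gave 81 calls, 74 of them shared. Merging entries by miRBase name gave no value, since all names are distinct. Depth limits calls below about 4.09 RPM, which is 3 reads in H/R replicate 1.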

Other observations

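For the short sequences the general-excess and tRNA tests, and for the single-library miRNAs every test was chosen only after the result was seen.

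Several fallen minor arms belong to the let-7, miR-125b and miR-374 hairpins, and the comparison above gave at most counts of them. let-7b-3p went from 53 ± 11.4 to 25.9 ± 3.74 RPM and let-7f-1-3p from 29.4 ± 4.43 to 14.1 ± 1.35 RPM (SD, n = 3 each), with limma adjusted p-values of 0.0396 and 0.0336. miR-125b-2-3p, whose -5p partner restrains differentiation genes in several tissues, fell from 741.0 ± 123 to 365.5 ± 60 RPM, and miR-374-3p from 164.6 ± 50.7 to 49.0 ± 15.5 RPM, each with limma adjusted p = 0.0149. miR-301a-5p fell from 90.8 ± 8.78 to 43.2 ± 5.77 RPM and is the more abundant arm of its hairpin in these libraries, unlike the others. Of the 25 known miRNAs that fell, 21 were the minor arm of a hairpin with both arms tested and 1 was the major arm. The 21 include let-7a-1-3p and let-7c-2-3p, which are the same sequence. The pairing kept the most abundant -5p and -3p arm of each hairpin name and left out the other 3. Among these 3, let-7c-1-3p and miR-125b-1-3p have a tested and more abundant -5p arm. These miRNAs were chosen after their values were seen.

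Over 131 hairpins with both arms tested, the minor arm fell against the major arm in H/R on average, with the lower log2 fold change in 85 hairpins (64.9%) and medians of −0.294 for minor and −0.12 for major arms. The mean log2 ratio of minor to major arm was −4.43 ± 0.053 in controls and −4.81 ± 0.071 in H/R (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible), and every H/R library lay below every control library. The difference was −0.381, and −0.377 without a pseudocount over 90 hairpins, a ratio that library scaling cannot change; after thinning all libraries to the same number of reads it was −0.375, which argues against depth. With GC content, length and level in the same model across the 262 arms of these hairpins, 114.4% of the minor-arm term remained, at −0.44 with a 95% interval of −0.66 to −0.21. This argues against a linear effect of base composition or length. The minor arm is by definition the less abundant one, so the model cannot fully separate level from arm. Its interval takes the sequences as independent, without the pairing of arms, and measures spread between sequences, not between libraries. A candidate explanation is that minor strands were lost faster, or made less, in H/R cells; it was not tested, and library preparation or RNA quality that differed between the groups is also open.

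The 103 predicted sequences of 17 to 19 nt had a median log2 fold change of 1.04 in H/R. After thinning the median was 1.163, so the lower depth of the H/R libraries is argued against. A general excess of short fragments, as from degraded RNA, may account for part of it: 48 of 55 sequences of 17 or 18 nt with at least 10 RPM had a log2 fold change above 0, 87.3% (15 of the 55 were called higher and 2 lower), and that share lies between the bounds set for and against it. Sequences with a mark of transfer RNA, a D-arm motif or a 3′ CCA end, had a median 0.064 above that of the others (permutation p = 0.8064), which leaves fragments of transfer RNA open; 6 with the D-arm motif had a median of 1.82 and 13 with the CCA end one of 0.66. The marked sequences were more abundant than the unmarked, with median levels of 767 and 6.08 RPM. The 14 sequences that rose from 0 control reads, given above, were all unmarked. Pairs of marked sequences had reads within 0.5%, 1.0% and 9.1% of each other in each library, yet the permutation took them as independent. The tRNA test therefore cannot decide the question. Degradation and a regulated release of fragments by H/R cannot be told apart here, because the origin of the sequences and the RNA quality were not analysed.

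Each H/R library, and no control, held known miRNAs with at least 50 reads at 5 times or more the level of any other library. They numbered 2, 6 and 5 in H/R replicates 1, 2 and 3, against 0 in each control, and took 0.098%, 0.095% and 2.916% of the totals; besides markers they were miR-212-5p (196.6 RPM), miR-338-3p (71.1 RPM) and miR-153-3p (26.5 RPM) in replicate 2 and miR-363-3p (189.6 RPM) in replicate 3, named after their values were seen. For the test of a shared response to H/R, known miRNAs were picked against the controls alone, without regard to the other H/R libraries. With at least 50 reads and 5 times the highest control in an H/R library there were 13, the same miRNAs as above. Only 1 of the 13 (7.7%), miR-144-3p, reached 5 times the highest control in another H/R library at any read number. This argues against a shared response for these miRNAs. Reads from another tissue in H/R replicates 2 and 3 are consistent with the markers fixed in advance, as 2 of these libraries held 3 or more such miRNAs with several from 1 list, namely 3 of 6 neural markers in replicate 2 and 4 of 9 blood markers in replicate 3, miR-142-5p (79.2 RPM) among them; whatever their reads, 4 of 6 and 7 of 9 were highest in these libraries, and miR-138-5p and miR-219a-5p lay below the highest control. Reads from another tissue in H/R replicate 1 cannot be told apart from other causes, because only 2 such miRNAs, both liver or epithelial markers, stood out there, although 7 of 9 markers of that list were highest in this library, most at few reads. The minimum of 50 reads is harder to reach in this shallowest library, where 1 read is 1.365 RPM against 0.465 RPM in replicate 2. It left out miR-375-3p, at 17.7 RPM (13 reads) against at most 1.86 RPM elsewhere. Whether such reads came in at culture, library preparation or sequencing was not tested in any of the H/R libraries.

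The labelled split of the 6 libraries gave 84 calls and the highest of the others gave 0; 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.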
